A study of Drosophila melanogaster with 24 samples.

How the data were processed

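Wing disc RNA of dmyc and cd2 larvae was measured on 24 two-colour arrays, 6 at each of 4 times (0, 12, 24 and 48 h). Per the labels' protocols, total RNA was amplified linearly in 2 rounds and reverse transcribed into Cy5 or Cy3 probes, with the dyes exchanged on 3 of the 6 arrays of each time. The deposited values are log2 ratios of the 2 RNAs on an array as far as the values show: they are centred on 0, with array medians between -0.01 and 0.008, and run from -7.19 to 5.68. The log base, scanner, background correction, normalization and any filter of the authors are not given in the sources used here, and base 2 was assumed. Signal over background is not part of the deposited log2 values, so the depth behind a single feature is unknown. Such compression or filtering as was applied upstream would carry through to every size given, and amplification can change the ratios of long and short transcripts unequally.

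For the direction check, each array was set against the mean of all arrays of its dye orientation, and the mean deviations of a time were correlated across genes between the orientations. The correlation was 0.84, 0.65, 0.73 and 0.50 at 0, 12, 24 and 48 h, over a bound of 0.05, so the deposited values of the 2 dye orientations run the same way within a time, and no array was turned. A pair with both partners reversed would not show in this check, and no separate test was made of the direction of single pairs. Features that differed in the same direction at every time, such as BaraB and grass, had that sign on 23 or 24 of 24 arrays. These features were picked for their constancy, so a feature reversed in a turned pair could hardly be among them. Their signs therefore cannot tell whether a pair was turned. Features at control position 2, a position inferred as described below, went from -1.67 on 0 h replicate 3 to 1.65 on 12 h replicate 6. That the ratio is dmyc over cd2 rather than the reverse rests on the order of names in the titles.

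The table held 12359 features, of which 169 at control positions were left out. Control positions were inferred as positions in a print block at which no feature named a gene. The block size was itself taken from the spacing at which unnamed features lined up best. Gene names came from the platform annotation, with 10289 features naming 1 gene, 56 naming several and 1845 naming none, and 9896 of those with 1 gene matched the RefSeq gene table. Features with several genes were not named. Each array was centred on its median, features of the same gene were averaged (1010 of 9011 genes had 2 or more), and a gene needed 4 or more values among the 6 arrays of each time. This left 8814 named genes and 1847 unnamed features, 10661 in all, with 1.58% of values missing. Features of the same gene were called in opposite directions for 2 genes at 0 h, 1 at 12 h, 4 at 24 h and 1 at 48 h, of 978 tested genes with several features. In the contrasts against 0 h this held for 19 genes at 12 h, 20 at 24 h and 0 at 48 h.

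The ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per time and 1 dye coefficient over all 24 arrays. Tested were each time against 0, each later time against 0 h, and any change over time by a moderated F test, with Benjamini-Hochberg adjustment over all features within a contrast and a threshold of 0.05. Gene lists with 5 or more measured members, 30 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry, for which missing values were filled with fitted values. The design, the alternatives listed at the outset, the gene lists and the rule for naming genes were chosen before the data were examined. The rule named dm, fwe, SPARC and azot, the 10 highest and 10 lowest genes of each time that passed with the same sign on every array measured, the 5 highest and 5 lowest of each contrast against 0 h. It also named up to 4 members of lowest p from each list with a call or with 3 or more members past the threshold.

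Dye-swap partners were found after the data were seen, as arrays of the same time and opposite dye that matched each other best (replicates 1 and 4, 2 and 5, 3 and 6, but 1 and 5, 2 and 6, 3 and 4 at 24 h). The correlation within pairs, fitted with duplicateCorrelation, was 0.443. Alternatives chosen at the outset were no centring, scaling, quantile normalization, complete genes alone, no minimum number of values, no dye coefficient, and a replicate block. Also chosen then were averages of replicates 1 and 4, 2 and 5, 3 and 6, array weights, robust eBayes, the compared arrays alone, features not averaged, the opposite turn of replicates 4 to 6, and leaving out each array. Added after the data were seen were partners averaged, partner pairs as a random block, each pair left out, a fat body covariate, and, for the lists, removal of each array's trend on gene span.

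The fits were tested on simulated data for the 12 h comparison with 10661 features. Simulated partners were given the same fitted correlation, 0.443, whatever the gene, except in the nucleolar list. The fit of 24 arrays then recovered 77.6%, 92.5% and 98.5% of changes of 0.25, 0.5 and 1 on the log2 scale. It made 68 false calls at 12 h, against 8 with partner pairs as a random block and 4 with partners averaged. The averaged fit recovered 56.7%, 91.0% and 98.5%. A simulated nucleolar list raised by 0.2 was called with the preset and the estimated correlation, with 0 other lists called. Genes were simulated independently of each other, and those of this list without the correlation of partners. The simulation therefore cannot tell how either setting fares where the genes of a list correlate. In the data, pairs correlated across genes at -0.81 to 0.65, and the fit with partners averaged called 0 features at 12 h. The false calls of the simulation thus need not match those in the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.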

Results

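RNA from larval wing discs, the epithelial sacs that form the adult wing, was compared on 24 competitively hybridised arrays. Discs of the genotype tub>dmyc>Gal4, in which the ubiquitous tubulin promoter drives the Drosophila Myc gene from a cassette that a heat shock can remove, were set against control discs of the genotype tub>cd2>Gal4, in which the cassette holds cd2. A short heat shock starts the formation of clones, so that cells with and without the cassette meet in one tissue, and discs were taken at 0, 12, 24 and 48 h, with 6 arrays at each time. The series addresses cell competition, in which cells with more Myc displace their neighbours, and its title concerns isoforms of a protein taken here to be the membrane protein encoded by flower (fwe). Replicates 1 to 3 held dmyc RNA in Cy5 and replicates 4 to 6 held it in Cy3. Every value below is a log2 ratio in which a positive number likely means higher in dmyc discs. The basis is the order of the names in the sample titles, together with the finding that the deposited values of both dye orientations already run the same way, and with the opposite order every higher or lower would change places. The log base is not given in the sources used here and was taken as 2. The standard deviation of the ratios over all features lay between 0.18 and 0.29 per array, and the number of arrays limits the precision.

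Each array correlated best with 1 array of the same time and opposite dye (r across genes 0.52 to 0.90), which was treated as its dye-swap partner. The labels do not say whether partners share RNA extracts, or whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Partners correlated (0.443 as fitted over all features), so the p-values and standard errors from 24 arrays are on the whole too small, whether or not extracts are shared. If partners share extracts, n is 3, not 6, at each time. Beside each count from 24 arrays stand therefore the counts with partner pairs as a random block and with partners averaged, both chosen after the data were seen. Genes given below as highest or lowest, or as rising or falling the most, are so among named genes that passed, at a single time with the same sign on every array measured. Some unnamed features had larger ratios. List members counted as higher, lower, rising or falling are those past the threshold. Each value after ± is the moderated SE of limma, with the spread of a gene pooled over all 24 arrays, not over the 6 of its time. It can be smaller or larger than the spread at that time gives. For LysE at 48 h the SD over 6 arrays was 1.48 and this SE 0.42, and for bel at 12 h they were 0.82 and 0.16.

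The transcript of dm, the gene for Myc, is not analysed here, so the transgene itself gave no check of the labels. The ratio of fwe was -0.48 ± 0.07 (SE, n = 6 arrays; adjusted p 0.000515) at 0 h, lower in dmyc discs on 6 of 6 arrays, with values from -0.61 to -0.33. It was 0.18 ± 0.07 at 12 h (adjusted p 0.136), 0.18 ± 0.08 at 24 h (5 arrays, adjusted p 0.164) and -0.02 ± 0.07 at 48 h (adjusted p 0.915), none of which passed the threshold. The fwe ratio rose from 0 h by 0.65 ± 0.10 at 12 h (adjusted p 0.000267), by 0.66 ± 0.11 at 24 h (adjusted p 0.000662) and by 0.45 ± 0.10 at 48 h (adjusted p 0.0173). The array carries 1 feature for fwe, which does not separate its isoforms. SPARC, a secreted glycoprotein of the extracellular matrix, followed a similar course, with -0.65 ± 0.08 at 0 h (adjusted p 0.000135, 6 of 6 arrays) and 0.23 ± 0.08 at 12 h (adjusted p 0.0605). Its ratio rose from 0 h by 0.88 ± 0.11 at 12 h (adjusted p 4.32e-05), by 0.72 at 24 h and by 0.61 at 48 h. The ratio of azot, a calcium-binding protein gene, was -0.04 ± 0.13 at 0 h and 0.60 ± 0.13 at 48 h (adjusted p 0.007, higher on 5 of 6 arrays), and the difference of 0.64 ± 0.18 passed the threshold (adjusted p 0.0395). With the mean of the fat body markers on each array as a covariate, azot was 0.31 at 48 h (adjusted p 0.249) and its difference was 0.38 (adjusted p 0.123), neither of which passed. That mean was above 0 in every 48 h pair (0.55, 1.06 and 0.34). The covariate thus overlaps with this time and cannot tell fat body RNA from an effect of dmyc.

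With partners averaged, the adjusted p of fwe was 0.0883 at 0 h and 0.0427, 0.0667 and 0.269 for the 12, 24 and 48 h differences. That of SPARC was 0.0679 at 0 h and 0.0351, 0.0728 and 0.256 for the differences, and that of azot was 0.199 at 48 h and 0.319 for its difference. The 48 h difference of fwe also lost its call with pairs as a random block (adjusted p 0.102) and without 0 h replicate 3 (0.0534). It lost it without the pair of 0 h replicates 2 and 5 (0.0839), of 0 h replicates 3 and 6 (0.0867) or of 48 h replicates 1 and 4 (0.069). At 24 h fwe passed without the pair of replicates 2 and 6 (0.37, adjusted p 0.0182). SPARC passed at 12 h without 12 h replicate 5 (0.0456), 24 h replicate 5 (0.0452) or 48 h replicate 2 (0.0424). It also passed without the pair of 12 h replicates 2 and 5 (0.0412), 24 h replicates 1 and 5 (0.0269) or 48 h replicates 2 and 5 (0.0373). At 48 h azot lost its call without the pair of replicates 1 and 4 (0.0561) or 2 and 5 (0.42, adjusted p 0.144), and with the 48 h arrays alone (0.0976). Its difference lost the call with pairs as a random block (0.129) and with no dye coefficient (0.0575). It lost it without 0 h replicate 2, 3, 5 or 6 (0.0838, 0.0796, 0.0752 or 0.0711) and without 48 h replicate 1, 2, 4 or 5 (0.0626, 0.0781, 0.0711 or 0.0723). Without the pair of 0 h replicates 2 and 5 or 3 and 6, or of 48 h replicates 1 and 4 or 2 and 5, its adjusted p was 0.15, 0.145, 0.106 or 0.142.

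**Figure D1:**
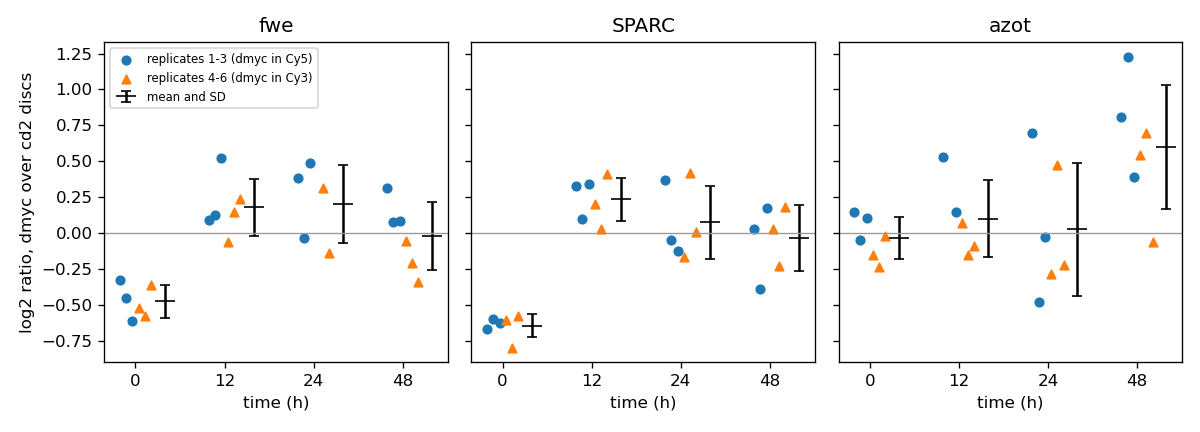
Log2 ratio of dmyc over cd2 discs (y axis) at each time in h (x axis) for fwe, SPARC and azot; points are arrays, with dmyc in Cy5 (circles) or in Cy3 (triangles), and black bars are the mean and SD over arrays. All 6 arrays at 0 h lie below 0 for fwe and for SPARC.

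At 0 h, Ance, a secreted peptidase related to angiotensin-converting enzyme, was the named gene lowest in dmyc discs (-1.62 ± 0.36 SE, n = 6, adjusted p 0.00563). Next came the ecdysone-inducible gene ImpE2 (-1.20 ± 0.29), the tubulin genes betaTub56D (-1.12 ± 0.25) and alphaTub85E (-1.06 ± 0.17), the actin gene Act79B (-1.05 ± 0.22) and the innexin gene Inx3 (-0.95 ± 0.20). Sec61alpha, the core of the protein channel of the endoplasmic reticulum, stood at -0.91 ± 0.17. The other places went to Spn100A and Spn43Aa, both serpins, and the peptidase gene SP1029. BaraB was highest in dmyc discs (0.88 ± 0.13). Next came CG4686 (0.62), CG9008 (0.51), the small nucleolar RNP gene Gar1 (0.47), Nepl3 (0.46), RpS27A (0.46), the cytochrome c oxidase genes COX5B (0.43) and COX7C (0.41), the cuticle gene Lcp65Aa (0.43) and Ssb-c31a (0.40). The random block of partner pairs removed the calls of RpS27A (adjusted p 0.118), Lcp65Aa (0.08) and Spn100A (0.0644). Once replicates 1 and 4 were left out, Nepl3 was 0.30 and passed, while CG9008 (0.27), Gar1 (0.30), Lcp65Aa (0.15), Spn100A (-0.57) and SP1029 (-0.52) did not. Once replicates 3 and 6 were left out, COX7C (0.27), ImpE2 (-0.67), Act79B (-0.64), Inx3 (-0.61) and RpS27A (0.15, and 0.25 without replicate 6 alone) did not pass. Of 61 mitochondrial ribosomal protein genes, 17 were higher and 2 lower (28 and 5 adjusted over the list alone), with a median of 0.11. The list was called higher by camera (adjusted p 1.35e-07), but with adjusted p = 0.711 with an estimated correlation. mRpS6 (0.25 ± 0.05) and mRpL17 (0.26 ± 0.06) were higher on all 6 arrays, and mRpL18 (-0.19 ± 0.03) was lower. Of 68 genes of oxidative phosphorylation, 13 were higher and 3 lower (18 and 6 adjusted over the list alone; camera adjusted p 0.00013, adjusted p = 0.711 with an estimated correlation). Among them were ND-B12 (0.24) and ox (0.38). Cytoplasmic ribosomal protein genes had 7 of 36 members higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p 0.0209, adjusted p = 0.711 with an estimated correlation). RpS21 stood at 0.36 ± 0.08, RpLP1 at 0.48 ± 0.11 and RpL3 at -0.47 ± 0.11. The wing pouch and disc patterning list was called lower (3 of 14 members, 5 adjusted over the list alone, adjusted p 0.0409, adjusted p = 0.711 with an estimated correlation). The pouch transcription factor gene nub stood at -0.26 ± 0.04, hh at -0.17 and ptc at -0.13. Markers of trachea, a tissue attached to the disc, were called lower at the same time (3 of 9 members, also 3 adjusted over the list alone, adjusted p 0.0409, adjusted p = 0.711 with an estimated correlation). The members that passed were the chitin deacetylase genes verm (-0.50 ± 0.09) and serp (-0.23 ± 0.06) and sinu (-0.34). Of the genes named from these lists, serp (adjusted p 0.106), sinu (0.0612), hh (0.0881) and ptc (0.0904) did not pass with partner pairs as a random block. When replicates 3 and 6 were left out, RpLP1 (0.16), RpL3 (-0.31), ox (0.24), sinu (-0.18), hh (-0.10) and ptc (-0.06) did not pass. RpLP1 was 0.32 without replicate 3 and RpL3 was -0.71 without the pair 1 and 4, and each passed. The pouch and trachea calls were lost with partners averaged (adjusted p 0.0629 and 0.054), quantile normalization (0.0812 and 0.0677), complete genes alone (0.236 and 0.107) and removal of the trend on gene span (0.104 for each). The pouch call was also lost with the fat body covariate (0.0724) and without 0 h replicate 1, 3, 4 or 6 (0.0588, 0.168, 0.0706 or 0.116), or 48 h replicate 3 (0.0509). Of pairs left out, it was lost without the 0 h pairs 1 and 4 (0.149) or 3 and 6 (0.392) and the 48 h pairs 1 and 4 (0.0563), 2 and 5 (0.0532) or 3 and 6 (0.0553). The trachea call was lost without 0 h replicate 1, 3 or 4 (0.0505, 0.0889 or 0.0706), 48 h replicate 3 (0.0509), the 0 h pairs 1 and 4 (0.123) or 3 and 6 (0.127) and the 48 h pair 1 and 4 (0.0563). The call of cytoplasmic ribosomal protein genes was lost without 0 h replicate 1 or 4 (0.0588 for each), without both (0.151) and without the pair 3 and 6 (0.0966). It was also lost with the trend on gene span removed (0.107) and with fry (0.147), which also left oxidative phosphorylation uncalled (0.0816).

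In all, 1287 of 10661 features passed at 0 h, 409 higher and 878 lower, and quantile normalization gave 610 and 655. Array weights, chosen at the outset, gave 3143 (1234 higher, 1909 lower). With the 0 h arrays alone 494 passed, and with averages of replicates 1 and 4, 2 and 5, 3 and 6, also chosen at the outset, 92 did. When partner pairs entered as a random block 515 passed, and with partners averaged 0 did in limma, where 1724 had an unadjusted p under 0.05. Without 0 h replicate 2, 3, 5 or 6 the count was 794, 553, 855 or 671, and without the pair of replicates 2 and 5 or of 3 and 6 it was 413 or 206.

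At 12 h, 4 of 14 heat shock genes and 13 of 36 nucleolar ribosome biogenesis genes were higher in dmyc discs. The chaperone gene Hsp68 stood at 1.30 ± 0.30 (SE, n = 6, adjusted p 0.0123), the Hsp40 cochaperone gene DnaJ-1 at 0.86 ± 0.14, Hsp26 at 0.75 ± 0.11 and Hsc70-2 at 0.38 ± 0.09, each higher on 6 of 6 arrays. These were the 4 members that passed of the 14 in the heat shock list (6 adjusted over the list alone). Camera called the list higher (adjusted p 0.00344, adjusted p = 0.25 with an estimated correlation), though not without the pair of replicates 1 and 4 (0.113). Discs of both genotypes received the heat shock. Of 36 nucleolar ribosome biogenesis genes, 13 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p 5.57e-09, adjusted p = 0.171 with an estimated correlation). Among them were Fib, the fibrillarin methyltransferase of the nucleolus (0.56 ± 0.10), Polr1A, the largest subunit of RNA polymerase I (0.39 ± 0.06), Surf6 (0.29 ± 0.05) and CG1542 (0.31 ± 0.06). BaraB (0.77), pst (0.74), the histone chaperone gene Nap1 (0.73), the RNA helicase gene bel (0.66), CG8545 (0.66), CG3984 (0.62) and CG3788 (0.60) filled the other places among the highest. Lowest were Ref2 (-0.96 ± 0.14), the semaphorin gene Sema1a (-0.69 ± 0.16), the serine protease gene grass (-0.60 ± 0.08), the cuticle gene Cpr51A (-0.58), the glutathione S-transferase gene GstO3 (-0.51), corto (-0.49), Ugt36D1 (-0.47), NimC2 (-0.46), CG3097 (-0.45) and CG34159 (-0.42). Of the DNA damage list, Ku80 (0.33 ± 0.04), mre11 (0.24 ± 0.06) and nbs (0.18 ± 0.05) were higher and the checkpoint kinase gene lok (-0.19 ± 0.05) was lower, while the list of 12 was not called by camera (adjusted p 0.359). Treated as a random block, partner pairs removed the calls of bel (adjusted p 0.124), CG3984 (0.0829), Sema1a (0.0517), Ugt36D1 (0.0546), NimC2 (0.139), CG3097 (0.0651), Hsc70-2 (0.0509), CG1542 (0.0509), mre11 (0.0865), nbs (0.189) and lok (0.112). One array carried much of the value of bel, which was 0.36 without replicate 5 and 0.40 without the pair 2 and 5, and passed in either case. CG3984 was 0.35 without replicate 4 and did not pass. Without the pair 1 and 4, Hsp68 (0.65), pst (0.40) and CG3984 (0.12) did not pass, and corto was -0.31 and did. Without the pair 3 and 6, Nap1 (0.41), Ugt36D1 (-0.29) and nbs (0.10) did not pass, and CG8545 was 0.44 and did. Without the pair 2 and 5, lok (-0.12) did not pass, and nbs was 0.27 and did.

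The 12 h count was 884, with 567 higher and 317 lower (475 and 389 with quantile normalization). With the 12 h arrays alone, an alternative chosen at the outset, it was 53 (39 higher, 14 lower), and 2 with averages of replicates 1 and 4, 2 and 5, 3 and 6. It was 143 with partner pairs as a random block and, with partners averaged, 0 in limma, where 1490 had an unadjusted p under 0.05. It fell to 480, 387 or 350 without 12 h replicate 1, 3 or 6 and to 294 without the pair of replicates 3 and 6.

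At 24 h, Gs2, the glutamine synthetase gene, was the named gene lowest in dmyc discs (-1.12 ± 0.26 SE, n = 6, adjusted p 0.0131). Next were Ref2 (-0.66 ± 0.14), the decapping enzyme gene DCP2 (-0.64), Ugt36D1 (-0.59), Sema1a (-0.58), the dystroglycan gene Dg (-0.52), ben (-0.52), Dek (-0.51) and the actin-bundling genes Fim (-0.51) and sn (-0.51). Highest were the protease gene Jon74E (0.85 ± 0.20, 4 arrays), Nap1 (0.78 ± 0.18), BaraB (0.76 ± 0.13), Act79B (0.75 ± 0.22), the lysozyme gene LysX (0.66), pst (0.58), alphaTub84D (0.56), the prohibitin gene Phb1 (0.56), Hsp26 (0.53) and eIF3d1 (0.52). The random block of partner pairs removed the calls of Jon74E (adjusted p 0.0734), Act79B (0.0896), LysX (0.0883), pst (0.0968), Phb1 (0.0544), DCP2 (0.0539), Sema1a (0.0953) and ben (0.072). When replicates 2 and 6 were left out, Jon74E (0.11) and LysX (0.095) did not pass, nor did LysX without replicate 2 alone (0.40) or pst without the pair 1 and 5 (0.34). The nucleolar list was called higher by camera again, with 4 of 36 members higher and 1 lower (10 and 1 adjusted over the list alone) and a median of 0.11 (adjusted p 0.00358, adjusted p = 0.679 with an estimated correlation). Fib stood at 0.36 ± 0.10, CG11837 at 0.27 ± 0.07, CG3071 at 0.19 ± 0.04 and Rrp1, lower, at -0.19 ± 0.03. In flies the symbol Rrp1 names recombination repair protein 1, a DNA repair gene, so its place among the 36 nucleolar genes is doubtful. Of 36 cytoplasmic ribosomal protein genes 4 were higher (also 4 adjusted over the list alone; adjusted p 0.0187, adjusted p = 0.679 with an estimated correlation). They included RpL3 (0.46 ± 0.11) and RpL17 (0.24 ± 0.06). Of 17 autophagy genes, Atg9 (0.25 ± 0.04) and Atg1 (0.15 ± 0.05) were higher (3 adjusted over the list alone; adjusted p 0.0359, adjusted p = 0.203 with an estimated correlation). Markers of gut and salivary gland were called higher in the same comparison, with 3 of 22 members higher (4 adjusted over the list alone; adjusted p 0.0129, adjusted p = 0.679 with an estimated correlation). These were ng1 (0.31 ± 0.07), Jon74E and LysX. Without the pair of replicates 2 and 6, in which the mean of the gut and salivary gland markers was 0.72, none of the 4 list calls held (adjusted p 0.0892 nucleolar, 0.944 ribosomal, 0.0629 autophagy, 0.86 gut and salivary gland). Without replicate 2 or 6 alone the ribosomal list (0.27 or 0.242) and the gut and salivary gland list (0.191 or 0.138) were not called. The autophagy list was not called without replicate 1, 2, 3 or 5 (0.0659, 0.0762, 0.057 or 0.0633), the pairs 1 and 5 (0.146) or 3 and 4 (0.0576), or the 0 h pair 1 and 4 (0.0537). With complete genes alone adjusted p was 0.0835 for the other 3 lists and 0.0844 for autophagy, and with fry it was 0.0553 nucleolar, 0.119 ribosomal and 0.0963 gut and salivary gland. With the trend on gene span removed the autophagy list was not called (0.0561). Of the list members named, Fib (0.084), CG11837 (0.0953), CG3071 (0.0719), RpL3 (0.0632), RpL17 (0.0802) and Atg1 (0.177) did not pass with partner pairs as a random block. Atg1 was 0.09 without replicate 3 and 0.07 without the pair 3 and 4, and RpL17 was 0.13 without the pair 2 and 6, none of which passed.

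The 24 h count was 868, with 400 higher and 468 lower, and quantile normalization gave 453 and 408, so which direction held more features depended on it. The count was 229 with the 24 h arrays alone, 13 with averages of replicates 1 and 4, 2 and 5, 3 and 6, 172 with partner pairs as a random block and, with partners averaged, 0 in limma, where 1435 had an unadjusted p under 0.05. It fell to 387, 561 or 321 without 24 h replicate 1, 3 or 5, to 139 without the pair of replicates 1 and 5 and to 576 without that of 3 and 4.

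At 48 h, 16 of the 36 nucleolar genes were higher in dmyc discs and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.19. This was the 1 list call of the series that held with an estimated correlation (camera adjusted p 1.9e-15, adjusted p = 0.0188 with an estimated correlation). The RNA polymerase I subunit genes Polr1B (0.34 ± 0.04 SE, n = 6) and Polr1A (0.42 ± 0.06), l(2)k09022 (0.57 ± 0.06) and Surf6 (0.33 ± 0.05) were each higher on 6 of 6 arrays. The fat body protein gene Fbp2 (2.22 ± 0.64, adjusted p 0.0422), the clotting gene fon (1.71 ± 0.51) and hll (1.14 ± 0.28) were the highest named genes. They were followed by BaraB (1.14 ± 0.13, adjusted p 1.09e-05), the cytochrome P450 gene Cyp4e3 (1.05), the neprilysin-family gene Nep6 (1.04), Pepck1, a phosphoenolpyruvate carboxykinase of gluconeogenesis (0.92), pst (0.92), Arms (0.88) and DnaJ-1 (0.86). Markers of the fat body, a tissue next to the discs in the larva, were called higher, with 2 of 11 members higher (6 adjusted over the list alone) and a list median of 0.20 and mean of 0.65 (adjusted p 0.000522, adjusted p = 0.396 with an estimated correlation). The lysozyme genes LysE (-1.75 ± 0.42) and LysS (-1.66 ± 0.41) were the lowest named genes. They were the 2 of 22 gut and salivary gland markers that passed (7 lower adjusted over the list alone; list adjusted p 0.000522, adjusted p = 0.764 with an estimated correlation). Without the pair of replicates 1 and 4, whose mean over these markers was -1.15, that list was not called (adjusted p 0.607), nor was it without replicate 1 alone (0.0505) or with fry (0.0655). Ref2 (-1.49 ± 0.14, adjusted p 2.95e-06), CG3097 (-0.87 ± 0.10), grass (-0.76 ± 0.08), CG4382 (-0.66), GstO3 (-0.55), CG14541 (-0.54), Gnpnat (-0.50) and CG5532 (-0.49) completed the lowest genes. Of 14 heat shock genes 3 were higher (3 adjusted over the list alone; adjusted p 0.0144, adjusted p = 0.396 with an estimated correlation). These were DnaJ-1, Hsp26 (0.56 ± 0.11) and CG7130 (0.29 ± 0.06). The call was lost without replicate 6 (adjusted p 0.0847) and without the pair of replicates 3 and 6 (0.202). Treated as a random block, partner pairs removed the calls of Fbp2 (0.075), fon (0.085), Cyp4e3 (0.051), Pepck1 (0.0531), LysS (0.0525) and CG7130 (0.0531). Fbp2 was 1.26 without the pair 2 and 5, and LysE and LysS were -0.91 and -0.80 without the pair 1 and 4, none of which passed.

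The 48 h count was 671, with 331 higher and 340 lower, or 263 and 251 with complete genes alone. With the 48 h arrays alone it was 132 (83 higher, 49 lower), and with averages of replicates 1 and 4, 2 and 5, 3 and 6 it was 146. The count was 204 with partner pairs as a random block, 58 with partners averaged and 119 with the mean of the fat body markers on each array as a covariate. That mean was above 0 in every 48 h pair, so the covariate overlaps with this time. The lower count thus cannot tell fat body RNA from an effect of dmyc at 48 h. Without 48 h replicate 2 or 5 the count fell to 322 or 380, and without both to 235. Ref2, BaraB, CG3097, grass, GstO3 and CG14541 still passed with partners averaged, at adjusted p 0.0175, 0.0216, 0.0197, 0.0216, 0.0279 and 0.012.

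**Figure D2:**
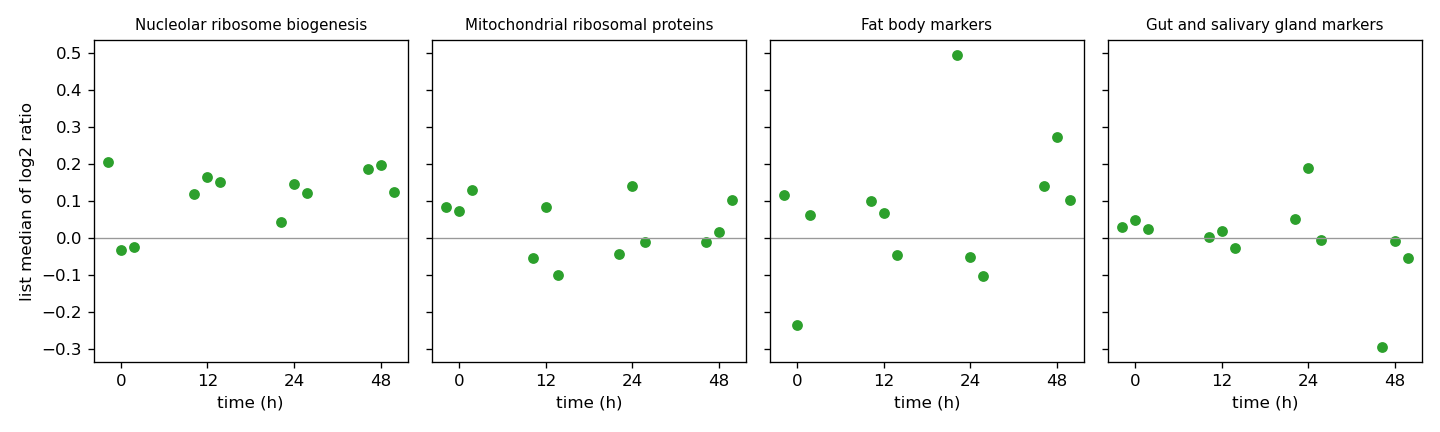
Median log2 ratio of dmyc over cd2 discs (y axis) of 4 gene lists, by time in h (x axis); each point is 1 pair of dye-swap partners, averaged. The nucleolar medians of all 9 pairs after 0 h lie between 0.04 and 0.20.

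The change of the ratio between 0 h and 12 h asks what differed after clones had formed beyond what differed at the start. Ance went from -1.62 to 0.86, a rise of 2.48 ± 0.50 (SE, 6 arrays at each time, adjusted p 0.00149), and ImpE2 rose by 1.78 ± 0.41, Act79B by 1.68 ± 0.32, betaTub56D by 1.58 ± 0.36 and alphaTub85E by 1.52 ± 0.25. The ratios of zfh2 (-0.84 ± 0.29), the ubiquitin-conjugating enzyme gene ben (-0.79 ± 0.20), nej, the histone acetyltransferase CBP (-0.75 ± 0.11), Ref2 (-0.67) and CG9008 (-0.66) fell. In the random block of partner pairs zfh2 (adjusted p 0.0757) and Ref2 (0.0527) did not pass, nor did Ref2 without the 12 h pair 1 and 4 (-0.39). CG9008 was -0.42 without the 0 h pair 1 and 4 and betaTub56D was 0.95 without the 12 h pair 3 and 6, and each passed. Of 61 mitochondrial ribosomal protein genes, 21 fell and 5 rose (24 and 6 adjusted over the list alone; median -0.13). Camera called the list lower (adjusted p 0.00135, adjusted p = 0.762 with an estimated correlation). Of these, mRpL51 (-0.24 ± 0.04) fell whereas mRpL4 (0.41 ± 0.07) and mRpL45 (0.40 ± 0.07) rose. Genes of oxidative phosphorylation were called lower, with 19 of 68 falling and 10 rising (26 and 10 adjusted over the list alone; adjusted p 0.0399, adjusted p = 0.762 with an estimated correlation). COX7C (-0.62 ± 0.12) and ATPsynG (-0.59 ± 0.13) fell and ND-42 (0.74 ± 0.14) rose. Trachea markers were called higher (4 of 9 rose, 5 adjusted over the list alone; adjusted p 0.0399, adjusted p = 0.617 with an estimated correlation). The rise was largest for verm at 1.01 ± 0.12 and serp at 0.51 ± 0.09. Without the pair of 12 h replicates 3 and 6 none of these 3 lists was called (adjusted p 0.0651 mitochondrial ribosomal, 0.277 oxidative phosphorylation, 0.0651 trachea). With the trend on gene span removed their adjusted p was 0.0803, 0.206 and 0.0926. With quantile normalization oxidative phosphorylation and trachea were not called (0.057 for each), and with complete genes alone they were not (0.0669 and 0.0622). Oxidative phosphorylation lost its call without 0 h replicate 1, 3 or 6 (0.0709, 0.0752 or 0.0682), 12 h replicate 3, 4 or 6 (0.0863, 0.115 or 0.0871), or 48 h replicate 4 (0.0518), and with partners averaged (0.0585). Of pairs left out, its call ended without the 0 h pairs 1 and 4 (0.097) or 3 and 6 (0.163), the 12 h pair 1 and 4 (0.0652) and the 48 h pairs 1 and 4 (0.0609) or 3 and 6 (0.0529). Trachea lost it without 0 h replicate 3 (0.0602), 12 h replicate 6 (0.0565), 48 h replicate 4 (0.0518), the 0 h pairs 1 and 4 (0.0587) or 3 and 6 (0.0641) and the 48 h pair 1 and 4 (0.0609). With fry adjusted p was 0.0633 for the mitochondrial ribosomal and 0.204 for the oxidative phosphorylation list.

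In total 2539 features changed between 0 h and 12 h, 1606 rising and 933 falling (1229 and 1226 with quantile normalization). With partner pairs as a random block 1322 did, with partners averaged 343, and with averages of replicates 1 and 4, 2 and 5, 3 and 6 877. Without the pair of 0 h replicates 2 and 5, of 0 h replicates 3 and 6 or of 12 h replicates 3 and 6, the count was 1590, 1254 or 1366. Of the 878 features lower at 0 h, 237 were higher at 12 h, against 46.7 for independent lists. The lists share the same fit and the same spread per gene, so the comparison with 46.7 is no test. Opposite profiles were also seen between pairs, with r across genes of -0.81 between 0 h replicates 3 and 6 and 12 h replicates 3 and 6, each pair averaged. No pair was turned, and no separate test was made of whether a whole pair runs the other way. The 2 features higher and 7 lower at all 4 times had that sign on 23 or 24 of 24 arrays. A turned pair would reverse both of its arrays, but a feature reversed in this way could hardly pass at all 4 times. The signs of features picked for their constancy therefore cannot tell whether a pair was turned. Control features at position 2 did change sign, from -1.67 and -1.475 in that 0 h pair to 1.42 and 1.65 in that 12 h pair. Pairs of the same time correlated at -0.13 to 0.49, with -0.13 between 0 h replicates 1 and 4 and 0 h replicates 2 and 5 and 0.06 to 0.20 among the 24 h pairs. Some pairs of different times correlated more, with 0.65 between 12 h replicates 3 and 6 and 24 h replicates 3 and 4 and 0.50 between 0 h replicates 1 and 4 and 48 h replicates 2 and 5. The cause of these correlations was not tested.

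Between 0 h and 24 h, Act79B (1.80 ± 0.32 SE, 6 arrays at each time, adjusted p 0.000862), ImpE2 (1.69 ± 0.41), betaTub56D (1.49 ± 0.36), Sec61alpha (1.47 ± 0.25) and CG8036 (1.42 ± 0.29) rose the most of the named genes. Gs2 (5 arrays at 0 h) fell by 1.65 ± 0.39, CG15353 by 1.47 ± 0.51 and the neuropeptide-like gene Nplp4 by 1.43 ± 0.42, and ben (-0.91) and nej (-0.79) fell as they had at 12 h. CG15353 did not pass with partner pairs as a random block (adjusted p 0.0786). Without the 0 h pair 1 and 4, Gs2 (-1.05), CG15353 (-0.81) and Nplp4 (-0.61) did not pass, nor did ImpE2 without the 24 h pair 3 and 4 (1.09). Of the 38 translation factor genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), among them eIF3d1 (0.86 ± 0.15) and eEF1alpha2 (1.17 ± 0.27), and the list was not called by camera (adjusted p 0.626). None of the 30 lists was called by camera. The count was 2163, with 1302 rising and 861 falling (1117 and 987 with quantile normalization). It was 3303 with array weights, 325 with averages of replicates 1 and 4, 2 and 5, 3 and 6, 920 with partner pairs as a random block and, with partners averaged, 0 in limma, where 2332 had an unadjusted p under 0.05. It was 1399 without 0 h replicate 3, and 1067, 741 or 1230 without the pair of 0 h replicates 2 and 5, of 0 h replicates 3 and 6 or of 24 h replicates 3 and 4.

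Between 0 h and 48 h, DnaJ-1 rose by 1.30 ± 0.19 (SE, 6 arrays at each time, adjusted p 0.00138), Nep6 by 1.06 ± 0.27, pst by 1.01 ± 0.24, Arms by 0.97 ± 0.20 and HnRNP-K by 0.89 ± 0.22. Ref2 (-1.20 ± 0.20), the cuticle genes Lcp65Aa (-0.64 ± 0.19) and Lcp9 (-0.50 ± 0.12), Ir76a (-0.51 ± 0.07, 5 arrays at 48 h) and the dynamin gene shi (-0.50 ± 0.13) fell. With partner pairs as a random block Nep6 (adjusted p 0.0843), pst (0.0826), Arms (0.054), HnRNP-K (0.102), Lcp65Aa (0.125), Lcp9 (0.0843) and shi (0.135) did not pass, which left DnaJ-1, Ref2 and Ir76a of these genes. Without the 0 h pair 1 and 4, Lcp65Aa (-0.37) did not pass and Lcp9 (-0.31) did. Without the 48 h pair 1 and 4 Lcp9 (-0.32) did not pass, nor did HnRNP-K without the 0 h pair 3 and 6 (0.57). Of the 36 nucleolar genes 7 rose and 0 fell (11 and 1 adjusted over the list alone; median 0.23, camera adjusted p 0.0002, adjusted p = 0.688 with an estimated correlation). CG8939 (5 arrays at either time) stood at 0.48 ± 0.12, l(2)k09022 (5 arrays at 0 h) at 0.41 ± 0.08 and CG11837 at 0.40 ± 0.09. These 3 genes did not pass with partner pairs as a random block (0.102, 0.0843 and 0.0976), nor did Lpin (0.123) and Npc2d (0.168). The fat body list was called higher by camera (adjusted p 0.0473, adjusted p = 0.688 with an estimated correlation), with a median of 0.26. Lpin (0.24 ± 0.06) was the 1 of 11 members that passed, also when adjusted over the list alone. Gut and salivary gland markers were called lower (adjusted p 0.0044, adjusted p = 0.688 with an estimated correlation), with a median of -0.17. Npc2d (-0.17 ± 0.05) was the 1 of 22 members that passed, also when adjusted over the list alone. The lists of mitochondrial ribosomal proteins (1 up and 2 down of 61, also adjusted over the list alone; adjusted p 0.0196) and oxidative phosphorylation (0 up and 4 down of 68, also adjusted over the list alone; adjusted p 0.0298) were called lower (adjusted p = 0.856 with an estimated correlation for each). Without the pair of 48 h replicates 1 and 4, adjusted p was 0.434 for the gut and salivary gland list, 0.434 for the mitochondrial ribosomal list, 0.459 for oxidative phosphorylation and 0.0985 for the fat body list. The mitochondrial ribosomal call was also lost without 48 h replicate 4 (0.0786), the 0 h pairs 1 and 4 (0.0867) or 3 and 6 (0.068) and the 48 h pair 2 and 5 (0.0926). Oxidative phosphorylation lost its call without 0 h replicate 1 or 3 (0.074 or 0.0659), or 48 h replicate 1, 2 or 4 (0.112, 0.101 or 0.0803), and with partners averaged (0.0537). It lost it as well without the 0 h pairs 1 and 4 (0.0867) or 3 and 6 (0.183) and the 48 h pair 2 and 5 (0.153). The fat body call was lost with partners averaged (0.0867), quantile normalization (0.0611), no dye coefficient (0.0588) and complete genes alone (0.208). It was lost without 0 h replicate 1, 2 or 5 (0.0596, 0.0787 or 0.0792), 12 h replicate 2, 3, 4, 5 or 6 (0.0517, 0.0516, 0.0525, 0.0511 or 0.0542), 24 h replicate 3 (0.0502) and 48 h replicate 2, 4, 5 or 6 (0.101, 0.0708, 0.0689 or 0.0688). Of pairs left out, it was lost without the 0 h pair 2 and 5 (0.202), the 12 h pairs 1 and 4 (0.0503), 2 and 5 (0.0583) or 3 and 6 (0.0639), the 24 h pair 3 and 4 (0.0521) and the 48 h pair 2 and 5 (0.153). With the trend on gene span removed adjusted p was 0.151 for the mitochondrial ribosomal list and 0.12 for oxidative phosphorylation and the fat body list, and with fry it was 0.363 for either mitochondrial list, 0.116 for gut and salivary gland and 0.069 for the fat body.

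The 48 h change covered 675 features, 403 rising and 272 falling (340 and 374 with quantile normalization). It covered 1853 (1131 and 722) with array weights, 250 (189 and 61) with the arrays of 0 h and 48 h alone and 0 with averages of replicates 1 and 4, 2 and 5, 3 and 6. With partner pairs as a random block the count was 14, and with partners averaged it was 0 in limma, where 1464 had an unadjusted p under 0.05. It was 1208, 269, 200, 324 or 198 without 0 h replicate 1, 2, 3, 5 or 6, and 424 or 416 without 48 h replicate 3 or 4. Leaving out the 0 h pairs 1 and 4, 2 and 5 or 3 and 6 gave 1699, 74 or 41, and leaving out the 48 h pairs 1 and 4 or 3 and 6 gave 352 or 429. Over all times, the moderated F test called 2103 features, 3624 with array weights, 11 with averages of replicates 1 and 4, 2 and 5, 3 and 6, 743 with partner pairs as a random block and, with partners averaged, 0, where 1834 had an unadjusted p under 0.05. The F count was 1362 without 0 h replicate 3, and 941 or 699 without the pair of 0 h replicates 2 and 5 or of 3 and 6.

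The times after 0 h shared more called features than independent lists would. All lists came from the same fit with the same spread per gene, so they are not independent. The numbers for independent lists are a guide and no test. At 12 h and 24 h, 162 features were higher at both times (21.3 for independent lists) and 98 were lower at both (13.9 for independent lists). At 24 h and 48 h, 55 were higher (12.4) and 78 lower (14.9), and at 12 h and 48 h 72 were higher (17.6) and 61 lower (10.1). At 0 h and 48 h, 38 were higher (12.7) and 59 lower (28.0) at both. Fewer than for independent lists were shared by 0 h and 12 h, with 11 higher (21.8) and 15 lower (26.1), and by 0 h and 24 h, with 4 higher (15.3) and 18 lower (38.5). Lower at 0 h but higher at 24 h were 121 (32.9), and higher at 0 h but lower were 62 at 12 h (12.2) and 32 at 24 h (18.0).

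**Figure D3:**
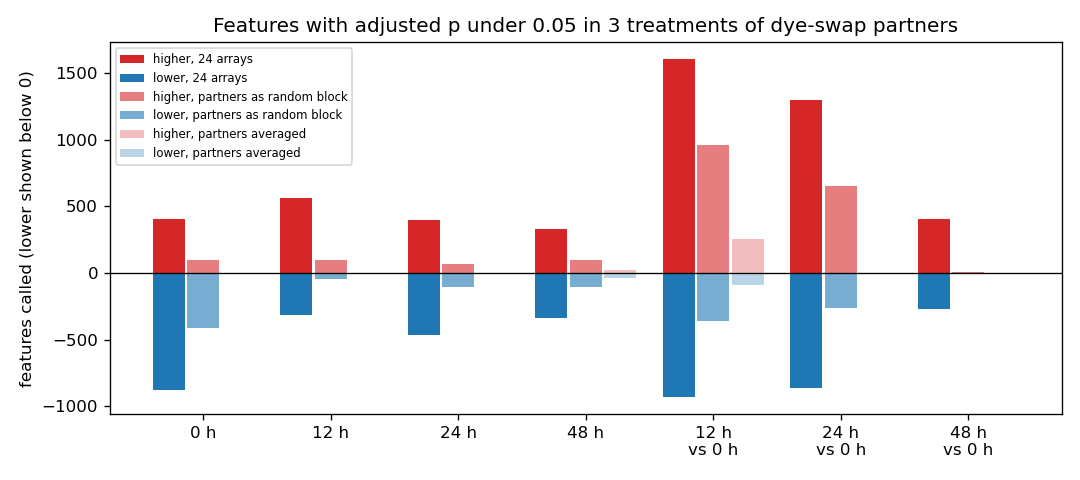
Number of features called higher (above 0) or lower (below 0) in dmyc discs, or with a rising or falling ratio against 0 h (y axis), for each comparison (x axis), with all 24 arrays, with partner pairs as a random block and with partners averaged. At 0 h the bars hold 409 higher and 878 lower features with all arrays, and 99 and 416 with the random block.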

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

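The tests of the fat body pattern, of single pairs in the nucleolar list and of splits that keep partners together were chosen only after the result was seen. On 4 of the 104 groups of 6 arrays examined, 1 array stood apart from the other 5, which chance gives in about 1 of 20 groups. Nepl3 at 0 h replicate 4 was 1.11 against 0.26 to 0.47 on the others (gap over range 0.758). The RNA helicase gene bel at 12 h replicate 5 was 2.25 against 0.11 to 0.76 (0.699), and its adjusted p of 0.0156 was 0.124 with partner pairs as a random block. Hsp26 at 12 h replicate 4 was 1.30 against 0.46 to 0.77 (0.636). The median of the heat shock list at 48 h replicate 6 was 0.27 against 0.03 to 0.11 (0.672).

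The dmyc to cd2 ratio differed between times, by a test of the difference itself, for 2539 features between 0 h and 12 h, 2163 between 0 h and 24 h and 675 between 0 h and 48 h, and for 2103 over all times. It differed for fwe by 0.65, 0.66 and 0.45 at 12, 24 and 48 h against 0 h, for SPARC by 0.88, 0.72 and 0.61, and for azot by 0.64 at 48 h, which was 0.38 and not called with the fat body covariate. Unnamed features at control positions, which entered no comparison, carried large ratios, with the lowest median of -5.16 at position 5 on 48 h replicate 1. The 0 h pairs differed in them. At position 4 the medians were -5.04 and -4.98 in replicates 1 and 4, against -0.40 and -0.50 in replicates 2 and 5 and -0.13 and -0.33 in replicates 3 and 6. At position 5 they were -4.62 and -4.30 in replicates 1 and 4, while replicates 2, 3, 5 and 6 held 8, 2, 5 and 0 of 20 values. At 12 h position 4 was 0.05 and 0.12 in replicates 1 and 4 and -1.56 and -1.60 in replicates 2 and 5. The 0 h count of 1287 was 1804 without replicates 1 and 4, 413 without replicates 2 and 5 and 206 without replicates 3 and 6. What these features are is not given in the sources used here, and that they are controls was inferred from their positions. The cause of the difference was not tested.

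With arrays taken as independent, 1 of 32 sign assignments gave as many features at each time, the real one, and 1 of 100 drawn splits did for each contrast and the F test. The highest of the others was 752 against 1287 at 0 h, 13 against 884 at 12 h, 62 against 868 at 24 h and 77 against 671 at 48 h. It was 1371 against 2539, 565 against 2163 and 111 against 675 for the contrasts, and 1077 against 2103 for the F test. Partners correlate (0.443), however, and most of these splits part them. With partners kept together there are 4 or 10 splits, too few for a share under 0.05, and the highest others were 524, 13, 62 and 57 at the 4 times and 885, 1026 and 364 for the 3 contrasts. For the F test 3 of 100 drawn splits with partners together gave as many, the real one included, a share under 0.05 that 100 draws fix only roughly. The highest of them called 3328, more than the real one, and the cause was not tested.

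Fat body genes swung between pairs of partners within a time. Obp99b was 2.36, -2.30 and 1.53 in the 3 pairs at 0 h and 5.04 in the pair of 48 h replicates 2 and 5, and Fbp2 was 2.31, -2.31, 1.19 and 4.13 in the same pairs. Pairs differed in the sign of the list mean at 3 of the 3 times before 48 h, which restates the swings and so tests no effect of the genotype, which stays open. RNA of fat body carried over with the discs is a candidate explanation that stays open. The 11 markers, 0 of them in another list, had a mean pairwise correlation of 0.236 over the 12 pairs, against a 95th percentile of 0.128 for random lists. They did not all swing, as bmm ran only from -0.05 to 0.26 and Lpin from -0.24 to 0.27. Moreover, apolpp and FASN1, also abundant in fat body, were 1.34 and -0.13 in the pair where Obp99b was highest. A biological change that differs between samples was not tested.

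The mitochondrial ribosomal protein list was called higher at 0 h, with medians of 0.08, 0.07 and 0.13 in the 3 pairs. Ratios at 0 h fell with gene span across genes (Spearman -0.186, and genes are not independent replicates). A trend with gene span as the whole cause is argued against, since camera still called the list with each array's span trend removed (adjusted p 0.000174). Gene span is not transcript length, so an unequal amplification of long and short transcripts was not tested and stays open. Carried-over fat body RNA is argued against, since camera still called the list with the covariate (adjusted p 1.36e-07). The call was lost with an estimated correlation (0.711), so a shift shared by correlated genes may account for it, and an effect of dmyc before clones form stays open and untested.

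The nucleolar list was called higher by camera at 12, 24 and 48 h (13, 4 and 16 of 36 members), and with an estimated correlation at 48 h alone (0.171, 0.679 and 0.0188). With the trend on gene span removed the highest adjusted p over these times was 0.00994, and with the fat body covariate it was 0.00671. This argues against either as the whole cause, while transcript length was not tested. A single pair is argued against at 12 and 48 h (highest adjusted p with a pair left out 9.17e-06). At 24 h the call ended without the pair of replicates 2 and 6 (0.0892), where the median went from 0.11 to 0.08, so 1 pair may carry that call. An effect of dmyc on these genes was not tested, and at 0 h the list was not called (adjusted p 0.137), with medians of 0.21, -0.03 and -0.02 in the 3 pairs. In the contrasts against 0 h, camera called the list at 48 h, but not with an estimated correlation (0.688), and did not call it at 12 or 24 h. Whether the ratios rose after 0 h is therefore not settled for 12 and 24 h.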

How the results depend on the processing

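Tests with partners averaged, partner pairs as a random block, pairs left out, the fat body covariate and the gene span trend were chosen only after the result was seen. Unless stated, the cause was not tested; fewer samples enter the fits with averages, left-out arrays or the compared arrays alone. No centring, scaling, no minimum number of values, no dye coefficient and robust eBayes kept every count of features within 1.5 times. Of 482 calls of named genes, 280 kept their side of the threshold with partner pairs as a random block, 40 with partners averaged, 424 with the fat body covariate and 448 with quantile normalization. Without 1 array 10732 of 11568 such calls held and without 1 pair 5026 of 5784. Of 23 list calls, 18 held with partners averaged and 1 with an estimated correlation. Whether replicate numbers pair the times is not settled. Same-numbered arrays correlated at -0.48 to 0.50 (median 0.05, against -0.01 for other numbers), and 8 of 24 arrays matched their own number best. Both measures lean weakly towards pairing, and neither was tested against chance. With the replicate block the counts were 1206, 767, 770, 649, 2404, 2032, 593 and 1950 (0, 12, 24 and 48 h, the 3 contrasts in time order, F test), and 1 list was called at 24 h against 0 h. The opposite turn was run for counts and fwe and not run for named genes and lists, since the direction check excluded it; nothing was run for dm, and the compared arrays alone give no separate F test. Arrays carry no signal over background here, so what dim features limit was not assessed.

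In the same order, averages of replicates 1 and 4, 2 and 5, 3 and 6 gave 92, 2, 13, 146, 877, 325, 0 (1869 at an unadjusted p under 0.05, limma) and 11 features. Partners averaged gave 0, 0, 0, 58, 343, 0, 0 and 0. Partner pairs as a random block gave 515, 143, 172, 204, 1322, 920, 14 and 743. The opposite turn of replicates 4 to 6 gave 0, 4, 0, 9, 0, 0, 0 and 0 (851, 935, 285, 1116, 59, 120, 406 and 208 at an unadjusted p under 0.05, limma). The compared arrays alone gave 494, 53, 229 and 132 at the 4 times and 250 for 48 h against 0 h. Array weights gave 3143 at 0 h, 3303 for 24 h and 1853 for 48 h against 0 h, and 3624 for the F test. The fat body covariate gave 119 at 48 h.

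Without 1 array the counts ranged from 553 to 1506 (0 h), 350 to 962 (12 h), 321 to 944 (24 h) and 322 to 704 (48 h). For the contrasts they ranged from 1864 to 2868, 1399 to 2446 and 198 to 1208, with 1362 to 2350 for the F test. Without 1 pair they ranged from 206 to 1804, 294 to 1072, 139 to 1063, 235 to 818, 1254 to 3026, 741 to 2677, 41 to 1699 and 699 to 2569. The fwe ratio ranged without 1 array from -0.52 to -0.43, 0.12 to 0.21, 0.12 to 0.26 and -0.07 to 0.03 at the 4 times and from 0.60 to 0.70, 0.60 to 0.74 and 0.40 to 0.50 for the contrasts. Without 1 pair it ranged from -0.50 to -0.46, 0.08 to 0.26, 0.071 to 0.37, -0.10 to 0.032, 0.55 to 0.73, 0.55 to 0.84 and 0.38 to 0.51. The numbers of lists called, 5, 2, 4, 4, 3, 0 and 5, ranged without 1 array from 2 to 5, 2 to 3, 1 to 5, 3 to 6, 1 to 4, 0 to 2 and 2 to 6. Without 1 pair they ranged from 2 to 7, 1 to 4, 0 to 5, 3 to 5, 0 to 5, 0 to 2 and 2 to 7.

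With an estimated correlation 0, 0, 0, 1, 0, 0 and 0 lists were called. With fry 5 were called at 12 h, 1 at 24 h and 10, 2 and 3 for the contrasts. Quantile normalization gave 3 lists at 0 h and 1 for 12 h against 0 h. Complete genes gave 3 at 0 h, 0 at 24 h and 1 for 12 h against 0 h; averages of replicates 1 and 4, 2 and 5, 3 and 6 gave 3 at 0 h. Partners averaged gave 3 at 0 h and 3 for 48 h against 0 h, and removal of the gene span trend gave 2 at 0 h, 0 for 12 h and 2 for 48 h against 0 h.

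The fwe ratio with the opposite turn was 0.011 at 0 h and 0.18 at 48 h, both of opposite sign, and 0.06, 0.13 and 0.17 for the contrasts, not called. With partners averaged it was -0.48 at 0 h and 0.72 and 0.45 for 24 h and 48 h against 0 h, not called. The last was 0.45 and not called with partner pairs as a random block and with averages of replicates 1 and 4, 2 and 5, 3 and 6. At 48 h, where fwe was not called, its sign changed without replicate 5 (0.00), replicate 6 (0.03), or the pair 2 and 5 (0.002) or 3 and 6 (0.032). Signs also changed for azot with quantile normalization (-0.041 at 24 h, -0.015 against 0 h), without 24 h replicate 1 (-0.09, -0.05), replicate 5 (-0.10, -0.06) or both (-0.25, -0.22), and at 0 h without replicates 2 and 5 (0.017). Without replicates 3 and 6 it was -0.074 there, and without 24 h replicates 2 and 6 it was 0.216 at 24 h and 0.252 against 0 h. For SPARC they changed at 48 h without replicate 2 (0.04), replicate 5 (0.005) or both (0.10) and at 24 h without replicates 1 and 5 (-0.085), and without 48 h replicates 3 and 6 it was -0.143 at 48 h. With features not averaged, 1 feature of ImpE3 gave 0.037 at 0 h, -0.108 for 12 h and -0.057 for 24 h against 0 h, and 1 of grp gave -0.078 at 48 h and -0.105 against 0 h. With the fat body covariate Obp99b was -0.019 at 48 h and Fbp2 -0.075 against 0 h, but both are part of that covariate, so these values say nothing about their stability.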

Other observations

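The test of neighbouring genes was planned before its result was seen, and the genes differing at all 4 times were noticed in the data. At 0 h, 4 of 11 members of the Hippo list, a pathway that limits organ growth, were lower in dmyc discs (4 adjusted over the list alone): Rassf (-0.25 ± 0.05 SE, n = 6), mats (-0.25 ± 0.05), the target gene fj (-0.29 ± 0.07) and yki, its transcriptional coactivator (-0.29 ± 0.08). Camera did not call the list (adjusted p 0.137), while fry called it lower (adjusted p 0.00834). Of these genes yki did not pass with partner pairs as a random block (adjusted p 0.0836). At 12 h 0 members of the list were higher and 1 was lower. Of 32 cell cycle and DNA replication genes, PCNA was higher at 0 h (0.34 ± 0.08) and E2f2 (-0.38 ± 0.08) and aurB (-0.23 ± 0.07) were lower (1 and 2 adjusted over the list alone). At 12 h E2f2 (0.31 ± 0.08) and aurB (0.25 ± 0.07) were higher and Cdk2 (-0.25 ± 0.06), Orc1 (-0.14) and Bub3 (-0.27) were lower. Of 14 cell death genes, Diap2 (-0.19 ± 0.05), the effector caspase gene Dcp-1 (-0.21 ± 0.06) and Dark (-0.17 ± 0.05) were lower at 24 h (3 adjusted over the list alone; list adjusted p by camera 0.268). With partner pairs as a random block aurB at 0 h (adjusted p 0.0824), E2f2 (0.0822), Cdk2 (0.0768), Orc1 (0.0917) and Bub3 (0.0713) at 12 h, and Diap2 (0.0953), Dcp-1 (0.105) and Dark (0.12) at 24 h did not pass. Without the 24 h pair 1 and 5 Diap2 (-0.12), Dcp-1 (-0.10) and Dark (-0.08) did not pass, and Dark was -0.27 without the pair 2 and 6. E2f2 was 0.19 at 12 h without the pair 3 and 6 and did not pass, and aurB was -0.37 at 0 h without the pair 1 and 4.

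Of 14 genes of the JNK pathway, Traf6 (-0.29 ± 0.05), Ask1 (-0.34 ± 0.08) and puc, the phosphatase that the pathway induces (-0.12 ± 0.04), were lower at 24 h and wgn (0.13 ± 0.03) was higher (2 higher and 3 lower adjusted over the list alone). The list was not called by camera (adjusted p 0.909). The ratio of puc rose between 0 h and 48 h by 0.37 ± 0.05. Of 18 genes of Toll and Imd immunity, key (-0.20), PGRP-LE (-0.15) and Tl (-0.41 ± 0.10) were lower at 24 h (3 adjusted over the list alone; list adjusted p by camera 0.0941). At 24 h wgn (adjusted p 0.09), Ask1 (0.0587), puc (0.159), PGRP-LE (0.0881) and Tl (0.0531) did not pass with partner pairs as a random block, and puc was -0.08 and did not pass without the pair 2 and 6. Of 38 translation factor genes, eIF3j (0.43 ± 0.07), eIF3h (0.43 ± 0.09), eEF1delta (0.31 ± 0.08) and eIF3g1 (0.28 ± 0.08) were higher at 12 h and 0 lower (9 and 0 adjusted over the list alone). The list was not called by camera (adjusted p 0.066) and was called by fry (0.0158), and eIF3h (0.0509), eEF1delta (0.098) and eIF3g1 (0.122) did not pass with partner pairs as a random block. Markers of blood cells, muscle, neurons and glia, and the germ line were not called by camera at any comparison, with lowest adjusted p of 0.268, 0.404, 0.657 and 0.378. With fry the germ line list was called at 0 h (0.042) and 48 h (0.0133) and the blood cell list between 0 h and 12 h (0.0405).

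At all 4 times 2 features were higher and 7 lower, against 0.0253 and 0.0366 if the 4 sets of calls were independent. The sets came from the same fit with the same spread per gene and are not independent, so this comparison is no test. BaraB (0.88, 0.77, 0.76 and 1.14 at 0, 12, 24 and 48 h, higher on 24 of 24 arrays) and CG7006 (0.16, 0.20, 0.14 and 0.24) were the higher ones. The lower ones were grass (-0.50, -0.60, -0.40 and -0.76), strat (-0.36, -0.21, -0.16 and -0.43), CG6583, CG5986, the ferritin heavy chain gene Fer1HCH and 2 unnamed features, of which 1 stood at -2.10, -2.43, -1.29 and -2.90. With partner pairs as a random block 2 of the features passed at all times, and with partners averaged 0 did. A hypothesis is that the 2 fly stocks differ in a stretch of the genome, which may make neighbouring genes differ together. Of the 7 named genes, 0 pairs lay within 10 tested genes of each other, but random sets of that size also had 0 at their 95th percentile, so the planned test could not separate the outcomes. Whether the stocks differ locally cannot be told apart from other causes.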
